A study of Homo sapiens with 2 samples.

How the data were processed

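RNA of 2 subclones of the HMC1 cell line was compared on Affymetrix U133 Plus 2.0 arrays. HMC1 is an established human line derived from mast cell leukaemia. The subclones had been separated by fluorescence-activated sorting with an antibody against CD2. One array was hybridised with biotin-labelled RNA of the CD2-positive subclone and the other with that of the CD2-negative subclone, so each group held 1 sample. RNA had been extracted with a Qiagen column kit, per the labels' protocols.

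The deposited values were probe-set intensity values on a linear scale, rounded to whole numbers, and the authors had normalised them with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, makes the probe intensities of all arrays follow 1 distribution by quantile normalisation and summarises the probes of a set on a log2 scale. The back-transformation to a linear scale and the rounding were seen in the values and are described in no source used here. Whether the background correction was that of standard RMA or one based on GC content is not given in the sources used here, and it would change low intensities and folds against them. Quantile normalisation removes any difference in total RNA signal between the arrays. Rounding makes low values coarse, since a difference of 1 unit is a large relative change there. No scanner images, cell-level intensities or detection calls were used here.

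Values were converted to log2, and every difference is the CD2-positive minus the CD2-negative array. Probe sets were named through the platform annotation: of 54675 probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 were not named by it. The last 2 kinds were left out of gene-level values. Entrez identifiers of 41043 of the 41097 probe sets were found in the RefSeq gene table of assembly GCF_000001405.40, which gave current symbols and the order of neighbouring genes. The files name no genome build, so no coordinates are given. Each of the 19775 genes was represented by its probe set with the highest mean log2 value over both arrays.

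A gene was compared where the higher array reached a log2 value of 6, an intensity of 64, which 3564 genes did. It was counted as higher or lower where the log2 difference was at least 1, which is 2-fold. With 1 array per group there is no estimate of the spread between cultures, so no p-value or standard error was computed, no difference has a replicate check, and nothing below is a test of the conditions. The number of arrays limits the precision of all values. The only spread that could be had lies within the arrays. Over 937 genes with more than 1 probe set above the floor, the log2 differences of the 2 brightest probe sets were compared. The standard deviation of the gap between them, divided by the square root of 2, was 0.13, as a value for 1 probe set. That value covers probe behaviour and not biological or hybridisation variation.

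Gene lists were written before the data were examined: 35 lists of adhesion receptors, mast cell genes, pathways and markers of other cell types. For each list with at least 5 members above the floor, the median log2 difference was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean level. The percentile describes these 2 arrays, and genes are not replicates. A list outside the central 95% of random lists is called outside the random range. On simulated arrays with 19775 genes, 92% of 200 genes changed by 1.5 on the log2 scale were recovered by the size rule. The genes to be changed were drawn only from genes well above the floor. The share therefore holds for brighter genes and does not describe recovery of genes near the floor. Of 200 random lists of 20 genes, 3.5% fell outside the random range without a shift, and 100% of lists shifted by 0.4 lay above it. Many lists reported below were shorter and had smaller medians, so the 100% does not describe them.

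The genes named in the text were fixed by rule beforehand: CD2; the 10 genes with the largest difference in each direction whose probe sets above the floor all had 1 sign; up to 4 members past the 2-fold rule from each list; where a list had none, its member with the largest difference; and KIT, CPA3, HDC, TPSAB1, FCER1A, CD58, CD48, CD59, IL2RA, ITGA4 and ITGB1. XIST and Y-linked genes were not named. Further list members given as examples were chosen after their values were seen. Alternatives were other floors (log2 5, 7 or none), other size rules (1.5-fold and 3-fold), the mean of all probe sets of a gene, only probe sets whose identifiers carry no _s, _x or _a, a requirement that all probe sets of a gene above the floor share a sign, centring on the median of all probe sets, and a lowess correction on mean level with a span of 0.3. A floor of log2 4, centring on the hybridisation controls and leaving out genes of shifted chromosome segments were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, with plots made in matplotlib 3.10.9.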

Results

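Gene expression was compared between 1 array of the CD2-positive and 1 array of the CD2-negative HMC1 subclone, to describe which adhesion receptors and other genes accompany surface CD2 in a line of neoplastic mast cells. Both arrays reported 54675 probe sets, with summed intensities of 1860969 in the CD2-positive and 1875750 in the CD2-negative sample and a median of 4 in each. Probe sets for Bacillus transcripts, which human RNA does not hold, read 1 to 4 on both arrays, and 56.5% and 56.9% of all probe sets lay at or below that level of 4. A value of 64 or more, the floor for comparing genes, was reached by 9.32% and 9.53% of probe sets. The 3' and 5' probe sets of GAPDH read 2911 and 2902 in the CD2-positive and 2567 and 2404 in the CD2-negative sample, and the ratio of 3' to 5' signal of ACTB was 1.38 and 1.59, respectively. All 18 probe sets for the bacterial and phage hybridisation controls read lower on the CD2-positive array, with a median log2 difference of -0.18 and a range from -0.40 to -0.04. Folds against values near 4 depend on the background correction, whose details are not given in the sources used here. There was 1 sample per subclone, so no difference below carries an error between replicates.

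CD2, the adhesion receptor used for sorting, read 219 in the CD2-positive and 13 in the CD2-negative subclone, a 16.8-fold difference (log2 difference 4.07). It was measured by a single probe set, and the difference follows the labels of the samples. The value of 13 in the CD2-negative sample lay above the level of the Bacillus probe sets. Among genes above the floor, LGALS3 and TUBA1A had larger positive differences than CD2. With the mean of all probe sets of a gene, the difference of LGALS3 was 3.43, below that of CD2.

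Across the 3564 genes above the floor, the levels of the 2 subclones were closely related, with Pearson's r of 0.94 and Spearman's rho of 0.91 across genes, which are not independent replicates. The middle 95% of the log2 differences lay between -0.68 and 0.70. In the CD2-positive subclone 43 genes were at least 2-fold higher and 27 were at least 2-fold lower, together 1.96% of the genes compared. The largest difference was that of LGALS3, which encodes the lectin galectin-3 and read 816 against 28, a 29.1-fold difference. Its other probe set, below the floor, read 8 against 2. With the mean of all probe sets LGALS3 had a log2 difference of 3.43, below that of TUBA1A (4.53). TUBA1A, an alpha-tubulin gene, read 139 against 6 and was 23.2-fold higher; alpha-tubulin genes are close in sequence, so its single probe set leaves the source among them uncertain. PRUNE2 was 7.22-fold higher, and TNS1, which encodes the actin-binding focal adhesion protein tensin-1, was 6.06-fold higher. GZMM, which encodes granzyme M, a serine protease known from cytotoxic lymphocytes, was 6.06-fold higher at 103 against 17. The chemokine gene CCL18 was 3.81-fold higher. ANXA2, encoding the membrane-binding protein annexin A2, read 247 against 39, a 6.33-fold difference, and its 3 probe sets above the floor gave log2 differences from 2.52 to 2.66. The annexin pseudogene ANXA2P2 was 3.78-fold higher, but its sequence is so close to that of ANXA2 that the 2 signals cannot be taken as separate.

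**Figure D1:**
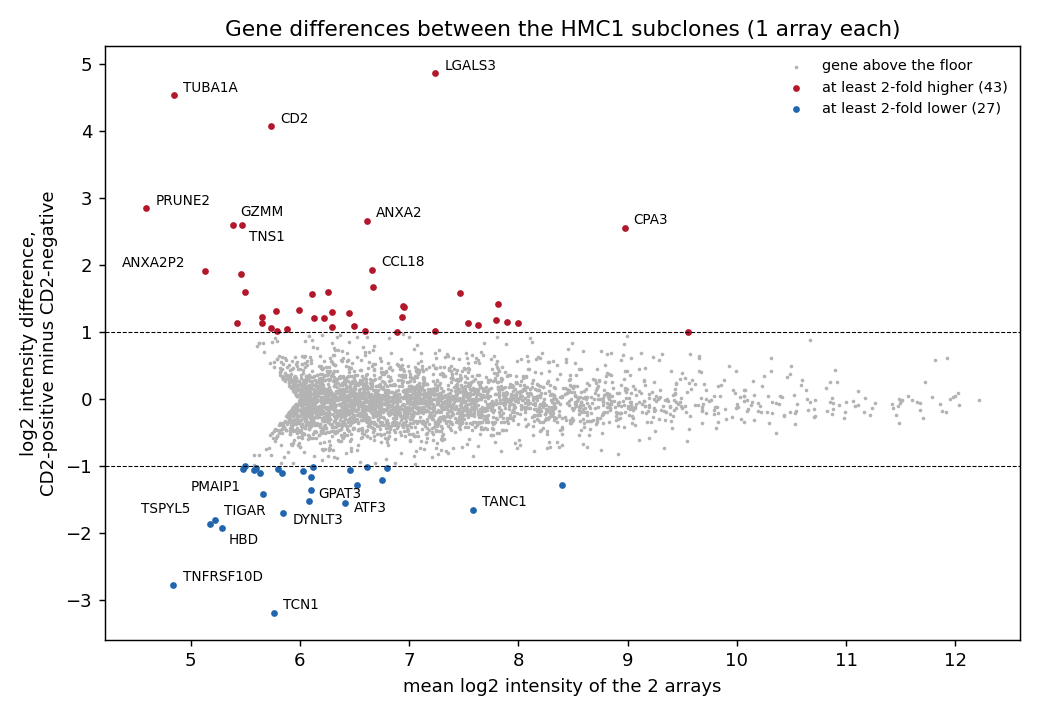
Log2 intensity difference (CD2-positive minus CD2-negative) against the mean log2 intensity of the 2 arrays, 1 point per gene above the floor, with dashed lines at 2-fold and 1 array per subclone. The 43 genes at least 2-fold higher include LGALS3, TUBA1A and CD2 at log2 differences above 4, and the 27 at least 2-fold lower reach -3.19 for TCN1; XIST and Y-linked genes are not drawn.

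In the other direction, TCN1, which encodes the vitamin B12-binding protein haptocorrin, read 18 in the CD2-positive and 164 in the CD2-negative subclone, a 9.11-fold difference. TNFRSF10D, a decoy receptor for the death ligand TRAIL, was 6.82-fold lower at 11 against 75. The delta-globin gene HBD was 3.80-fold lower, with a probe set that closely related globin genes leave uncertain, TSPYL5 3.63-fold lower and TIGAR, a regulator of glycolysis, 3.50-fold lower. The dynein light chain gene DYNLT3 was 3.25-fold lower and TANC1 3.15-fold lower at 108 against 340. ATF3, a stress-induced transcription factor gene, was 2.92-fold lower. GPAT3, an enzyme gene of glycerolipid synthesis, was 2.88-fold lower, and PMAIP1, which encodes the pro-apoptotic protein NOXA, was 2.68-fold lower. ATF3 on chromosome 1 and PMAIP1 on chromosome 18 lie among neighbouring genes whose medians were also negative (-0.34 and -0.36). No gene past the 2-fold rule had probe sets above the floor with opposite signs, but only 16 of the 70 genes had more than 1 such probe set. Centring on the hybridisation controls, which moves the median difference of all compared genes from -0.05 to 0.14, changed the split from 43 higher and 27 lower (61.4% higher) to 71 higher and 14 lower (83.5% higher).

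Adhesion receptors were the subject of the study. Immunoglobulin-type and other cell adhesion molecules were slightly higher in the CD2-positive subclone: of 18 members above the floor 16 had a positive and 2 a negative difference, and the median of 0.27 lay at the 99.99th percentile of random lists. NRCAM, a neuronal cell adhesion molecule of the immunoglobulin family, was the list's only member past the 2-fold rule, at 123 against 50 (2.46-fold). Smaller differences were measured for BSG, which encodes basigin (0.50), the tetraspanin gene CD81 (0.41), the leukocyte adhesion molecule ICAM3 (0.41) and JAM3 (0.41). The 6 integrin genes above the floor had a median of 0.19, within the random range. The largest difference was that of ITGAX, which encodes the integrin CD11c, at 103 against 62 (1.66-fold), and the beta-1 integrin gene ITGB1 read 453 against 397 (1.14-fold). ITGA4, the alpha-4 integrin gene, read 3 and 2, at the level of the Bacillus probe sets. Of the selectins and selectin ligands only SELPLG, encoding a selectin ligand, was above the floor, at 168 against 113 (1.49-fold). Cadherins and junction proteins had 5 members above the floor, with a mean of 0.11 and a median of -0.01 that becomes 0.17 when centred on the hybridisation controls. CDH17 was the one farthest from 0 at 66 against 37 (1.78-fold). The 8 focal adhesion and cytoskeleton linkers had a median of 0.06 and a mean of -0.01, and ZYX, which encodes zyxin, read 79 against 109 (1.38-fold lower). Both of these lists lay within the random range. Extracellular matrix and protease genes lay above it, with a median of 0.25 over 10 members at the 99.4th percentile, led by the cathepsin D gene CTSD at 103 against 53 (1.94-fold). The list was within the random range with the mean of all probe sets (percentile 85.7), with no floor (50.2) and with plain probe set identifiers (97.2).

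Genes of CD2 ligands and CD2 signalling went both ways. Among 9 members above the floor, 6 had a positive and 3 a negative difference. Their median of 0.07 and mean of -0.03 differ in sign, and the median lay within the random range. The negative members CD48 and CD244 (-0.60) lie on chromosome 1 among neighbours with a median of -0.31. Without genes of such segments the list's median was higher, as given below. FYN, a Src-family kinase gene, was 2.15-fold lower in the CD2-positive subclone at 34 against 73, and under 2-fold when centred on the hybridisation controls (-0.92). CD58, which encodes the main ligand of CD2, read 92 against 73 (1.26-fold higher). CD48, which encodes a related ligand, read 288 against 311, a log2 difference of -0.11 that becomes 0.07 when centred on the hybridisation controls. CD59 read 321 against 211 (1.52-fold higher), and its probe sets above the floor gave log2 differences from 0.40 to 0.86.

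Mast cell genes were higher in the CD2-positive subclone. Of 24 members above the floor, 21 had a positive and 3 a negative difference, and 3 were at least 2-fold higher and none at least 2-fold lower. The median of 0.36 lay above every one of the 10000 random lists. CPA3, which encodes mast cell carboxypeptidase A3, read 1220 against 207, a 5.89-fold difference. HPGDS, the haematopoietic prostaglandin D synthase gene, was 2.34-fold higher at 187 against 80, and the pseudogene SIGLEC17P was 3.04-fold higher. The tryptase gene TPSAB1 read 4806 against 3142 (1.53-fold), and its 4 probe sets above the floor gave log2 differences from 0.56 to 0.72. Tryptase genes are nearly identical in sequence, so this signal cannot be assigned to 1 of them. The histidine decarboxylase gene HDC, for the enzyme that makes histamine, read 1715 against 1219 (1.41-fold). KIT, encoding the stem cell factor receptor, read 1373 against 1328 (1.03-fold). FCER1A, the alpha chain gene of the IgE receptor, lay below the floor at 27 against 8. ALOX5 was the member with the most negative difference (-0.59). Surface markers described on neoplastic mast cells, a list that includes CD2 itself, had 13 of 21 measured members above the floor and a median of 0.12 within the random range. FAS, the death receptor gene, was 2.31-fold lower at 71 against 164, with 4 probe sets above the floor between -1.22 and -1.09. IL2RA, which encodes CD25, read 3 and 4, at the level of the Bacillus probe sets.

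**Figure D2:**
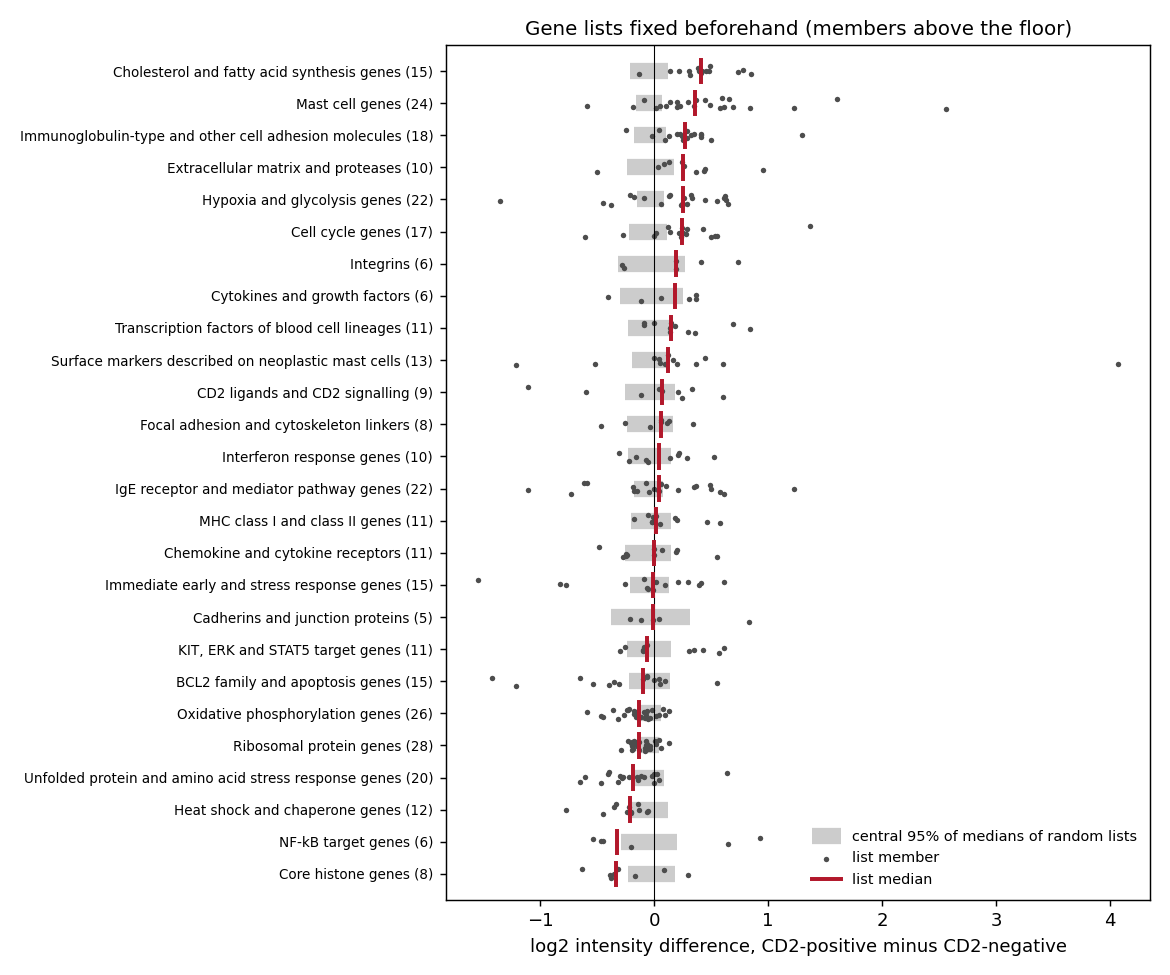
Log2 intensity difference (CD2-positive minus CD2-negative, 1 array each) of each list member above the floor (points), the list median (red bar) and the central 95% of medians of 10000 level-matched random lists (grey band), for the 26 lists with at least 5 such members (number in brackets). Mast cell genes and cholesterol and fatty acid synthesis genes have medians of 0.36 and 0.41, to the right of their bands, and core histone genes a median of -0.34, to the left.

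Cholesterol and fatty acid synthesis, hypoxia and glycolysis, and cell cycle genes had small positive medians above the random range. Cholesterol and fatty acid synthesis genes were higher in 14 of 15 members, with a median of 0.41 above every random list. LSS, the lanosterol synthase gene, led them at 117 against 65 (1.80-fold), followed by ELOVL6 (0.78) and FADS2 (0.74), genes of fatty acid elongation and desaturation. Hypoxia and glycolysis genes had a median of 0.25 at the 99.98th percentile, with 16 of 22 members positive. The most positive members were ALDOC (0.65), TPI1 (0.63), ENO2 (0.63), P4HA1 (0.62) and BNIP3 (0.55). Of the 6 negative members only PGK1 is a glycolytic gene, at -0.09 and on chromosome X among neighbours with a median of -0.47. MXI1 (-0.45), KDM3A (-0.37), NDRG1 (-0.21) and P4HA2 (-0.18) were also negative. The median was not taken for hypoxia genes apart from glycolytic ones. ADM, which encodes adrenomedullin, was 2.56-fold lower at 43 against 110. Cell cycle genes had a median of 0.25 at the 99.94th percentile, with 14 of 17 members positive. RRM2, a ribonucleotide reductase subunit gene on chromosome 2 among neighbours with a median of 0.27, was 2.58-fold higher at 199 against 77. PCNA, on chromosome 20 among neighbours with a median of -0.37, had the most negative difference (-0.61). Cell cycle genes were within the random range at a floor of log2 7 (percentile 95.2) and with the mean of all probe sets (97.4), and hypoxia and glycolysis genes with plain probe set identifiers (97.0).

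Core histone, NF-kB target, chaperone, unfolded protein and amino acid stress response, and ribosomal protein genes had small negative medians below the random range. When centred on the hybridisation controls, the medians of the first 4 stayed negative at -0.15, -0.14, -0.03 and -0.01, in that order. The core histone list, which also holds the linker histone gene H1-2 (-0.36), had a median of -0.34 over 8 members, at the 0.18th percentile. H2AC6 read 62 against 96. Of the members 6 were negative, and the 2 positive ones were H2AZ1 (0.09) and H2AX (0.30). Histone genes are close in sequence, so single members are uncertain. NF-kB target genes had a median of -0.33 over 6 members, at the 1.09th percentile. Their mean was -0.01. TNFAIP3 (-0.54) and NFKBIA (-0.45) were among the 4 negative members, and the 2 positive ones were CCL2 (0.65) and CD83 at 135 against 71 (1.90-fold higher). All 12 heat shock and chaperone genes above the floor had negative differences, with a median of -0.21 at the 1.26th percentile, and HSPA6 read 68 against 116 (1.71-fold lower). Unfolded protein and amino acid stress response genes had a median of -0.19 at the 1.13th percentile, with 15 of 20 members negative. XBP1 read 58 against 91, and TRIB3, on chromosome 20 among neighbours with a median of -0.37, had a difference of -0.60. Ribosomal protein genes had a median of -0.14 at the 0.64th percentile with RPS19 at 3030 against 3696, and their median turned to 0.05 when centred on the hybridisation controls. Ribosomal protein genes were within the random range with the mean of all probe sets (percentile 5.89), no floor (2.56) and plain identifiers (11.97), unfolded protein and amino acid stress response genes with the mean (3.77) and no floor (3.08), and heat shock and chaperone genes at a floor of log2 7 (2.90). Against random lists not matched on level, these 3 lists lay at percentiles 8.16, 2.66 and 3.57, also within the random range. In all, 6 of the 26 lists lay above and 5 below the random range, against 1.30 of 26 independent lists given by chance. The 1.30 also takes the genes within a list to vary independently, which genes of 1 pathway need not do. The excess is therefore no test.

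The remaining lists with a median lay within the random range as described, though transcription factor, oxidative phosphorylation, IgE pathway, cytokine and BCL2 family genes were outside it under some other settings. BCL2 family and apoptosis genes had a median of -0.10, which turned to 0.08 when centred on the hybridisation controls and was -0.36, below the random range, over the 7 members at a floor of log2 7. PMAIP1 and FAS were their only members past the 2-fold rule, both lower. Immediate early and stress response genes had a median of -0.01, which likewise turned positive (0.17), with ATF3 past the rule. KIT, ERK and STAT5 target genes had a median of -0.06 and a mean of 0.13, and the median turned to 0.12 in the same way. EGR1, an early growth response gene, read 648 against 424 (1.53-fold), with a log2 difference of 0.20 for its other probe set above the floor. Oxidative phosphorylation genes had a median of -0.14, which turned to 0.05. NDUFA1, on chromosome X among neighbours with a median of -0.47, read 480 against 721. IgE receptor and mediator pathway genes had a median of 0.04 with HPGDS higher and FYN lower past 2-fold. Medians were 0.15 for transcription factors of blood cell lineages, 0.18 for cytokines and growth factors, 0.05 for interferon response genes, 0.02 for MHC class I and class II genes and 0.00 (mean -0.04) for chemokine and cytokine receptors. Their members farthest from 0 were MITF, the master regulator of mast cell and melanocyte genes, at 276 against 154 (1.79-fold), IL16 at 50 against 66, RSAD2 at 95 against 66, HLA-DPA1 at 765 against 512, and IL18R1 at 120 against 82. RSAD2 lies on chromosome 2 among neighbours with a median of 0.27. The chemokine list had 3 members above the floor and CCL18 past the rule.

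In 6 lists of markers of other cell types most genes were at the level of the Bacillus probe sets in both subclones. These were 24 of 30 measured T and NK cell genes, 11 of 16 B cell and plasma cell genes, 21 of 24 monocyte, macrophage and dendritic cell genes, 14 of 19 neutrophil, eosinophil and basophil genes, 10 of 16 erythroid and megakaryocyte genes, and 15 of 23 fibroblast, endothelial and epithelial genes. Of stem and progenitor cell genes only 6 of 20 were at that level. The perforin gene PRF1 was the only member of the T and NK cell list above the floor, at 1060 against 1081; GZMM and CD2, which these cells also express, were above the floor but not in that list. AIF1 read 368 against 331, and the keratin gene KRT19 read 197 against 198. PRG2, the eosinophil major basic protein gene, read 2213 against 1194 (1.85-fold higher). In the erythroid and megakaryocyte list 3 members were above the floor, all lower, and HBD was past the rule. Stem and progenitor cell genes had 2 members above the floor, of which MYB read 176 against 109 (1.61-fold). The B cell list had no member above the floor.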

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

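The floor of log2 4, the centring on the hybridisation controls and the comparison without shifted chromosome segments were chosen after the result was seen. No paired analysis was possible because each subclone had 1 array, and no replicate could be left out. CD2 has a single probe set with a plain identifier, so the mean of probe sets and plain identifiers could not change its difference of 4.07. Median centring, a shift of 0, moves nothing. The difference of CD2 was 4.09 with lowess and 4.26 when centred on the hybridisation controls. Counts of genes higher and lower, 43 and 27 as reported, were 77 and 48 with a floor of log2 5, 24 and 8 with log2 7, 102 and 79 with log2 4, and 307 and 380 with no floor, where rounded background values enter. They were 151 and 134 with a 1.5-fold rule, 15 and 7 with a 3-fold rule, 26 and 13 with the mean of all probe sets, and 25 and 12 with only plain probe set identifiers; the last 2 compared fewer genes (1783 and 1970). Centring on the hybridisation controls gave 71 and 14. It moved the medians to 0.25 for CD2 ligands and signalling, 0.37 for integrins, 0.45 for immunoglobulin-type and other cell adhesion molecules and 0.54 for mast cell genes. The same centring reversed the median of ribosomal protein genes (0.0467). It cannot move a list's percentile, since list and random lists shift alike. Without a floor, medians were 0.00 for integrins and 0.13 for immunoglobulin-type and other cell adhesion molecules (99.98th percentile). Mast cell genes had a median of 0.49 with the mean of all probe sets. Without genes of the shifted chromosome segments described below, counts were 38 and 18, the median of CD2 ligands and signalling was 0.21, and all 11 lists kept their side. Of the 11 lists outside the random range, 6 of 10 with a median stayed with the mean of probe sets, 5 of 8 with plain identifiers, 6 of 8 at log2 7 and 8 of 11 with no floor; the lists that did not are named above. Lists that left the random range were transcription factors (floors of log2 4 and 5, no floor, lowess), oxidative phosphorylation (log2 4 and 5, no floor), the IgE pathway (0.18 with the mean of probe sets, and no floor), BCL2 family genes (log2 7), integrins (log2 4) and cytokines (log2 5). Among 26 named genes past the rule besides CD2, 22 stayed past 2-fold with the mean of probe sets, 25 with hybridisation-control centring (not FYN), and 26 with lowess. With plain identifiers 16 of the 20 that have such a probe set did so. The mean for FAS, FYN, ATF3 and TANC1 takes in probe sets that read 4 or less on both arrays, and the plain sets of ANXA2, FAS, FYN and ATF3 read 4 or less on both, so the former are diluted and the latter measure no difference. Interferon response genes turned from 0.05 to -0.05 without the segments and at log2 5, -0.06 at log2 4 and -0.07 with plain identifiers. The cause of the other moves was not tested. Signal near background limits genes below the floor, where values of a few units are rounded.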

Other observations

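The tests on handling stress, on GC content, on the whole X chromosome and on the position of p53 target genes were chosen after the result was seen, as was the scan of neighbouring genes. Genes named here outside the rule were chosen after their values were seen. The 2 prostaglandin D synthase genes went opposite ways: HPGDS was 2.34-fold higher and PTGDS 2.43-fold lower in the CD2-positive subclone, at 217 against 528. Besides ANXA2, the annexin gene ANXA1 was 2.01-fold higher at 1061 against 529. The chemokine gene CCL23 was 3.01-fold higher and the activation marker gene CD69 2.08-fold higher. PAG1, which encodes a membrane adaptor that restrains Src-family kinases, was 2.15-fold higher, and the plasminogen activator gene PLAT was 2.44-fold lower.

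Genes that differed between the subclones were not spread evenly over the chromosomes. In windows of 25 neighbouring genes above the floor, 212 of 3003 windows had medians beyond 0.24 or -0.32, limits that the most extreme window stayed within, on each side, in 95% of 1000 shuffles of the gene order. They formed 6 segments with 396 genes, 11.1% of those compared. The first 46 compared genes of chromosome 2, from ACP1 to SUPT7L, were higher (median 0.27, 40 of 46 positive). Lower segments were the last 101 of 156 compared genes of chromosome X from MSN on (median -0.47, 94 negative), 40 genes of chromosome 18 from RMC1 on (median -0.36), the first 27 of chromosome 20 up to NAA20 (median -0.37), and 65 and 117 genes of chromosome 1 (medians -0.31 and -0.34). The lower segments, with 9.82% of the genes compared, held 9 of the 27 genes at least 2-fold lower. The segment of chromosome 2, with 46 of 3564, held 4 of the 43 at least 2-fold higher. The segments were drawn from the same differences, so these counts give no separate support. Against the pattern, ITM2A in the lower segment of chromosome X was 3.05-fold higher.

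A candidate explanation is that the subclones differ in the copy number of these segments. If expression followed dosage, a change from 3 to 2 copies would give a log2 difference of -0.585, and one from 2 to 3 copies 0.585. The segment medians were smaller in size, from -0.31 to -0.47 for the lower segments and 0.27 for chromosome 2. Other changes in copy number would give other sizes, and the copy numbers of the subclones are not known here. For chromosome 2 the pattern was first seen in RRM2, NBAS, ITGB1BP1, LBH and MYCN, and the 40 other compared genes between the outermost of these had a median of 0.26, above every random list (0.44 when centred on the hybridisation controls). On chromosome X the 146 compared genes not among the largest differences in either direction had a median of -0.32, below every random list (-0.14 with that centring). Some of the 146, such as NDUFA1, are also members of the gene lists reported above. A level-dependent trend between the arrays as the whole cause is argued against by its size. The lowess correction above the floor lay between -0.078 and -0.003, and after it the medians of these chromosome 2 and X genes were 0.30 and -0.29. Their place beyond every random list after the correction adds nothing, since the random lists were already matched on level and shift nearly alike. A GC content bias as the whole cause should also lower the genes of chromosomes 4 and 13, which are the poorest in GC, but their median was -0.0553, at percentile 32.6 of random lists. A small GC trend stays open: of the GC-rich chromosomes, 16 (0.04) and 19 (0.03) lay above the random range and 17 and 22 (0.00 each) within it, while 2 (0.02) and 14 (0.02) also lay above it. A change of the whole X chromosome is argued against by the 55 compared genes of its short arm, a border set by the reference and not by the differences, whose median was -0.0075. Expression alone leaves open whether copy number or regional regulation differs, and with 1 sample of each subclone neither can be tied to CD2.

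Several genes known as targets of the transcription factor p53 were among those lower in the CD2-positive subclone, among them TNFRSF10D, TIGAR, PMAIP1, FAS and MDM2, which was 2.08-fold lower and under 2-fold when centred on the hybridisation controls. A list of p53 target genes was written after that was seen, and 17 of its members above the floor were not among the largest differences in either direction. These had a median of -0.36, at the 0.03rd percentile of random lists, with 16 of 17 negative. As 7 of the 17 are also in lists of the report, they are not a wholly fresh set. Among the 17 were TRIAP1 (-0.78), GADD45A (-0.77), GDF15 (-0.73) and CDKN1A (-0.27), and the only positive one was CD82 (0.33). The median was -0.34 after the lowess correction and -0.18 when centred on the hybridisation controls, and 0 of the 17 lay in the shifted segments. A general stress response to sorting or handling stays open: the immediate early and stress response genes went both ways (median -0.0074), while heat shock and chaperone and unfolded protein response genes were also lower (percentiles 1.26 and 1.13). A lower p53 output in the CD2-positive subclone, or a higher one in the CD2-negative subclone, may be a difference between these 2 cultures; growth conditions and chance differences between single cultures stay open.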
